A study of Zea mays with 3 samples.

How the data were processed

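Nuclear RNA was measured with a droplet method (10x Genomics 3′ gene expression) in nuclei of endosperm, the triploid nutritive tissue of the maize kernel. The plants were of the inbred line B73, and the labels put 3 replicates in 1 group. Per the labels' protocols, each preparation came from 10 endosperms of 3 ears that were chopped in buffer and passed through a mesh of 100 µm. The filtrate was stained with propidium iodide at 20 µg/mL, and about 100000 nuclei were sorted by fluorescence and loaded on the chip. Kit chemistry version 3 served for replicate 1 and version 3.1 for replicates 2 and 3. The age of the kernels is not given in the sources used here.

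The deposited matrix of replicate 1 holds counts, that is unnormalised unique molecular identifiers (UMIs) per gene and barcode. The authors made it with Cell Ranger, and Seurat is named as a further tool, per the submitters' processing notes. Versions, genome build and annotation are not given in the sources used here. The count matrices of replicates 2 and 3 were not analysed here, and for these libraries barcode lists alone were used. Each feature file was the same for all libraries. It listed 46430 features and gave a name to 6541 of them, among these 4692 of 44146 nuclear gene models, so genes are described by those names and otherwise counted. No coordinates are printed. KIL1 and KIL2, the factors in the title of the series, carry no such name among the features, and no NAC gene was taken to be either of them.

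The analysis used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9. Nuclei with at least 500 UMIs and at most 5% organelle UMIs were kept, and every barcode had at least 1147 UMIs, so the first limit removed none. Scrublet called 0 doublets. In a check with 200 sums of 2 nuclei added to the data it also called 0 of them, and 11.0% of them lay in the upper 5% of scores. The doublet caller therefore did not work here and doublets remain in the data. Counts per nucleus were scaled to the median depth and log-transformed. Genes in at least 10 nuclei were used, 401 genes of the result lists were left out, and 2000 highly variable genes, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 0.5 with seed 0 followed. Organelle genes, ribosomal RNA and Plant_SRP features, and markers outside the result lists were not left out.

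The level of a gene or list in a cluster is its summed UMIs over all UMIs of that cluster, expressed as counts per 1000000 UMIs (CPM). It was divided by the CPM of all other kept nuclei to give a fold. Only the matrix of replicate 1 was analysed here, so there is no spread between replicates and no test was made, since nuclei are not replicates. Intervals are exact at 95% (Poisson for CPM, conditional binomial for folds, Clopper-Pearson for shares of nuclei) and cover counting error only. For a list, the median log2 fold of members with at least 50 UMIs was placed among 10000 random lists of the same size drawn from genes of similar mean expression, as a description of this library. A prior count of 0.5 was added to UMIs for these member folds. Counts of members at least 2-fold higher or lower use these folds. They set no minimum of UMIs in the cluster, so in a small cluster a rare member can pass on very few UMIs. Shares of nuclei with a UMI of a gene were taken after thinning each nucleus to 1000 UMIs, with the unthinned share beside them. For phosphate transporter3 and Zea mays MADS6 only unthinned shares were taken.

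Gene lists, cell type markers and the rule for named genes were fixed before the data were examined. Marker lists covered starchy endosperm, aleurone, basal endosperm transfer layer, embryo surrounding region, endosperm adjacent to scutellum, embryo, green maternal tissue and cycling nuclei. Result lists covered NAC factors, cell death proteases and nucleases, autophagy, SWEET and amino acid transporters, starch synthesis, zeins, invertases, cell wall modification, defence, lipases, oil bodies and globulins, heat shock, ribosomal proteins, core histones, cell cycle, auxin, ethylene and imprinted genes. The wording used to match list names to the names in the feature file was adapted after those names were read and before counts per gene were seen. The amino acid transporter list matched 0 names and has no result. A cluster could take a name when at least 3 detected markers of a type were 1.5-fold higher in it than in other nuclei and its leading genes did not go against the name. Cluster 8 kept its number although 6 of 13 starchy endosperm markers were raised in it, since these are abundant in every cluster. Cluster 9 kept its number although 9 of 13 transfer layer and 14 of 44 cycling markers were raised, since its named leading genes are in neither list. In clusters 5 and 10 all 5 leading genes are unnamed, so leading genes could not go against their names. Clusters 2, 3, 4 and 12 also kept their numbers, with markers of more than 1 type raised. Clusters 5 and 11 were named although 4 of 44 cycling markers were raised in each. In cluster 5, 2 of 3 markers of endosperm adjacent to scutellum and 2 of 13 transfer layer markers were raised as well, under the limit of 3. In cluster 11, so were 2 of 13 transfer layer and 1 of 8 aleurone markers. The limit of 1.5 and these judgements were made after the data were seen.

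The rule named every marker with at least 50 UMIs, the 3 members of each result list with most UMIs and the 3 with the largest fold, and the 5 leading genes of each cluster at 4-fold and 100 CPM or more. It gave 193 pairs of a gene and a cluster with at least 3 UMIs. The text names 55 of these and 14 further genes, not counting features and markers given only to describe a cluster. Both choices were made after their values, and their behaviour under other settings, had been seen, so the named genes are a selection and are not a fair sample of the 193. Leading genes were picked by their fold in the cluster. Those outside the result lists were also open to clustering, so their folds are not independent of the cluster. Near-identical families (zeins, core histones, the SWEET4 genes) share sequence, and how the deposited counts split them is uncertain.

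The calculations were checked on simulated counts. The fold and list checks drew summed counts from the pooled profile of all kept nuclei. These draws hold no differences between nuclei, so the coverage of intervals below reflects counting error alone. For clusters 9, 10 and 11, exact intervals held the true fold of 96.7%, 96.8% and 97.3% of 19795 genes. Genes made 8-fold higher with at least 100 CPM were found at 4-fold in 27 of 27, 26 of 27 and 25 of 27 cases, and 0 unchanged genes reached that size in each. Of 100 unchanged lists of 10 genes in cluster 11, 6 lay above the 95th percentile, and 20 of 20 lists made 2-fold higher did so. Clustering of nuclei drawn from 12 profiles gave 11 clusters with an adjusted Rand index of 0.874. Nuclei drawn from 1 profile at the real depths still gave 2 clusters, with 64.0% in the larger, so nuclei of the same profile can be divided. Whether depth or counting noise divided them was not tested.

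Alternatives planned before the data were examined were other limits on nuclei, Leiden resolutions of 0.25 and 1.0, 1000 variable genes, 15 components, all genes allowed in clustering, clusters and levels taken from separate random sets of UMIs, another seed, means over nuclei, lists without their most abundant member, and other thinning. After the data were seen, 3 were added, which used only nuclei with at most 50000 UMIs, left out the upper 5% of Scrublet scores, or clustered 1000 UMIs per nucleus.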

Results

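Single-nucleus transcriptomes of B73 maize endosperm were examined to ask which kinds of nuclei the tissue holds and where genes tied to cell death, NAC regulation, sugar transport and storage are transcribed. The title of the series concerns NAC-type KIL factors and the removal of endosperm beside the embryo. The labels give 1 group, endosperm, with 3 replicates. Levels come from replicate 1 alone, so the differences have no replicate check, and ranges in parentheses are exact 95% intervals for counting error only. Replicate 1 held 3842 barcodes with 53733444 UMIs. Depth ran from 1147 to 708348 UMIs per barcode with a median of 4463, and the median barcode had 2709 genes. The 3833 nuclei kept held 53701253 UMIs, of which 178 nuclei with more than 50000 UMIs held 48.01%. A single gene, glycine-rich protein1, took 5.05% of UMIs and ranged from 21760 to 73760 CPM over clusters.

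The nuclei formed 12 clusters, numbered by size. Cluster 5 was aleurone-like (the outer endosperm layer) with 5 of 8 detected markers raised. Cluster 10 was cycling-like with 23 of 44, and cluster 11 resembled endosperm adjacent to the scutellum, the embryo's absorbing organ, with 3 of 3. Other clusters kept their numbers. Shares of nuclei were 6.71% (5.93 to 7.54) for cluster 5, 2.51% (2.03 to 3.05) for cluster 10 and 1.41% (1.06 to 1.83) for cluster 11. Clusters 1 and 2 held 25.3% and 24.2% of nuclei. Median depth ran from 2135 UMIs in cluster 2 to 23980 in cluster 8. A fluorescence sort of nuclei came before loading and can set these shares. At resolution 0.25, clusters 4 and 5 shared 1 matched cluster of 560 nuclei (Jaccard index 0.523 and 0.459), with 14.6% of nuclei. The best match of cluster 10 held 0.496% when clusters and levels came from separate UMIs.

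**Figure D1:**
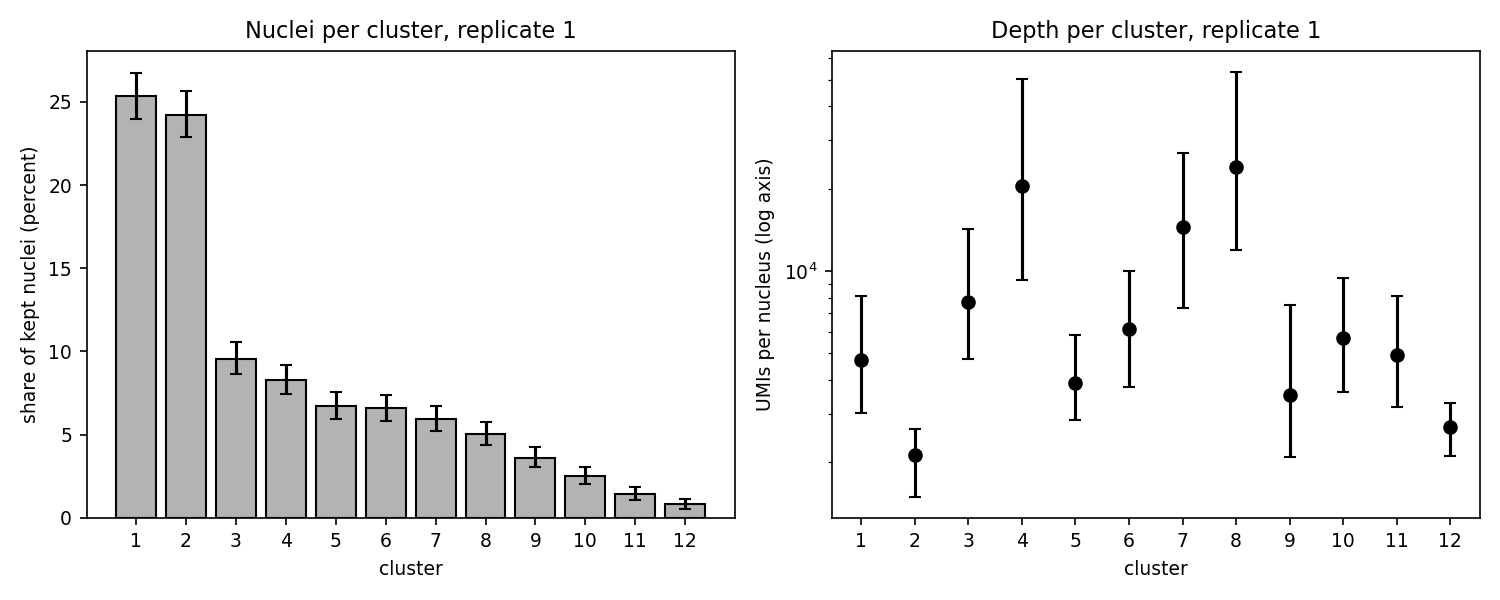
Left, share of the 3833 kept nuclei of replicate 1 in each cluster (bars, percent, with exact 95% intervals); right, UMIs per nucleus on a log axis (points, medians; lines, quartiles). Clusters 1 and 2 hold 25.3% and 24.2% of nuclei, and median depth runs from 2135 UMIs in cluster 2 to 23980 in cluster 8.

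In cluster 11, sugar efflux carriers of the SWEET family were higher than in other nuclei. The 23 members summed to 583.5 CPM against 122.6, a fold of 4.76 (4.16 to 5.42). Of the 10 with at least 50 UMIs, 5 were at least 2-fold higher and 3 at least 2-fold lower. SWEET14b (Zm00001d049252) reached 185 CPM, 23.6-fold (18.2 to 30.3) above other nuclei on 75 UMIs. SWEET14a (Zm00001d007365) was 15.1-fold (10.7 to 20.8) and SWEET15a (Zm00001d050577) 11.2-fold (6.25 to 18.6) higher, the latter on 16 UMIs. These 3 genes also gave the cluster its name, so their height is not independent of it, although SWEET genes were left out of clustering. SWEET4c was 3.44-fold (2.71 to 4.31) higher, in a family whose counts are uncertain. UMIs of SWEET14b were present in 27 of 54 nuclei, and in 20.4% (10.6 to 33.5) after thinning. In cluster 1 the thinned share was 0.824% and the unthinned share 3.81%, at median depths of 4949 and 4731 UMIs. The median log2 fold of the list was 0.67, at the 94.8th percentile of matched random lists.

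Single NAC genes and other transporters were also higher in cluster 11, while the NAC list as a whole was not, at 0.982-fold (0.924 to 1.04), with 13 of 56 members at least 2-fold higher and 6 at least 2-fold lower. Its median member lay at the 11.6th percentile of matched random lists. With 404458 UMIs in the cluster, rare members can reach 2-fold on very few UMIs, so the count of 13 does not show a raised subset. NAC-transcription factor 65 (Zm00001d025861) was at 131 CPM, 14.3-fold (10.6 to 19.1) above other nuclei, with UMIs in 21 of 54 nuclei (38.9%) against 4.12% in cluster 1, and after thinning in 7.41% (2.06 to 17.9) against 0.309% (0.0638 to 0.900). NAC-transcription factor 36, named outside the rule after its values were seen, was 10.5-fold (5.99 to 17.2) higher on 17 UMIs. Phosphate transporter3 reached 1031 CPM, 27.2-fold (24.4 to 30.2), with UMIs in 54 of 54 nuclei against 11.8% in cluster 1, both unthinned. Auxin transporter-like1 was 10.5-fold (7.40 to 14.5) and male sterile8 23.9-fold (17.0 to 33.0) higher. Phosphate transporter3 and male sterile8 were picked as leading genes of the cluster and were open to clustering. Their height is therefore not independent of the cluster. The starch-degrading enzymes beta amylase5 and beta amylase2, also chosen after their values were seen, were 59.6-fold (32.7 to 104.8) and 12.1-fold (8.87 to 16.1) higher. The deepest nucleus held 9.06% of the cluster's UMIs. With separate UMIs for clusters and levels, NAC-transcription factor 65 stood at 9.12-fold and beta amylase5 at 27.8-fold.

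**Figure D2:**
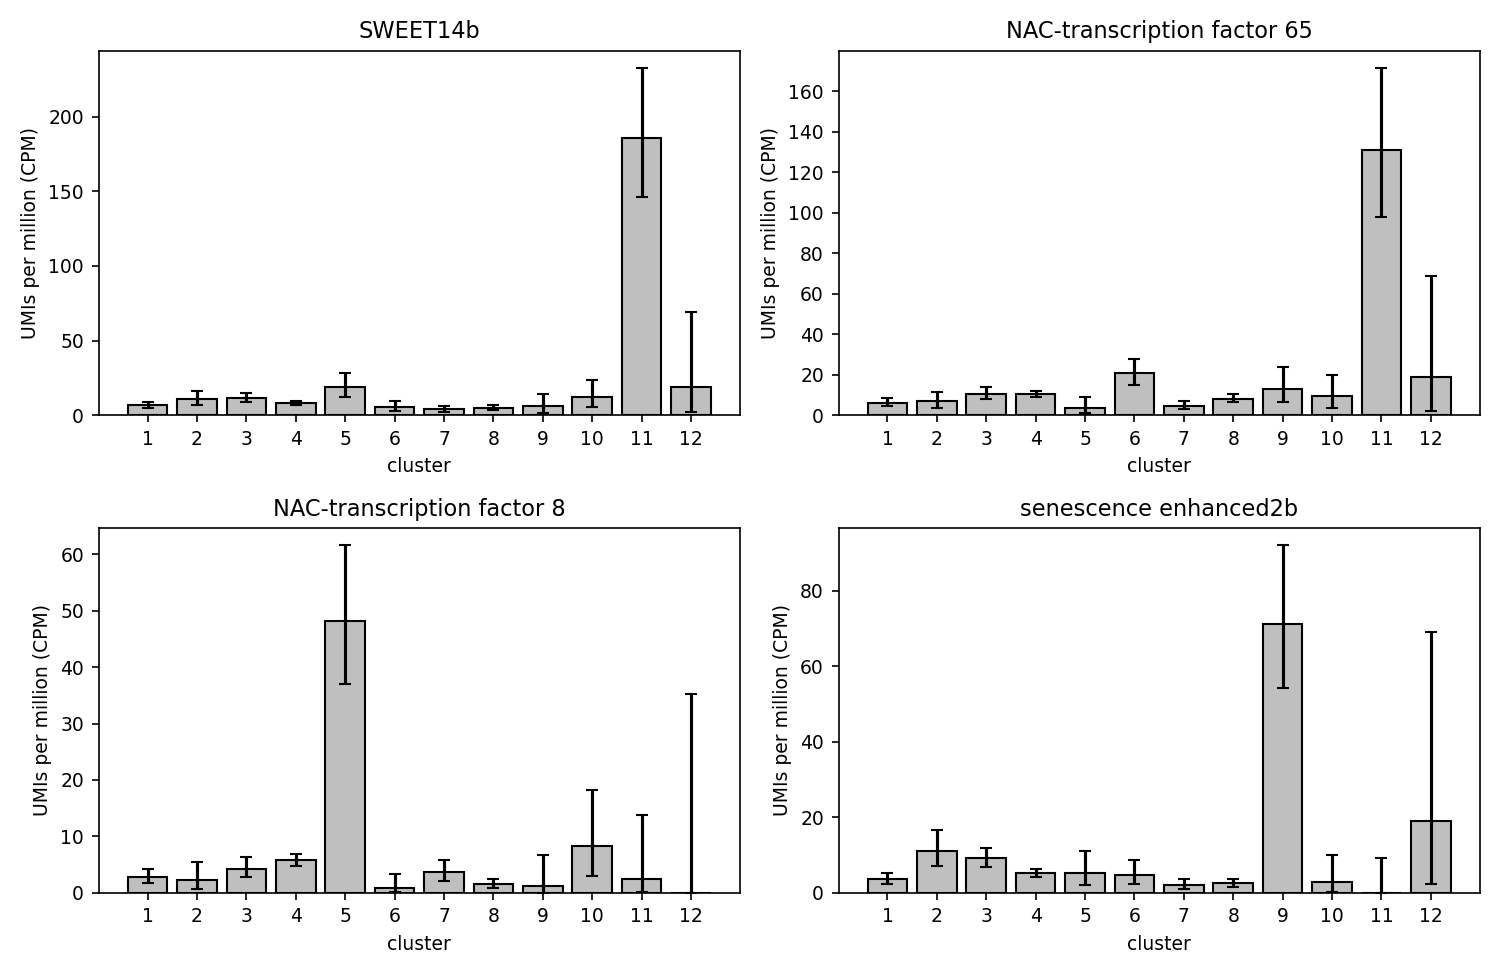
Level of 4 genes in each of the 12 clusters (bars, CPM with exact Poisson 95% intervals, replicate 1). SWEET14b and NAC-transcription factor 65 were highest in cluster 11 (185 and 131 CPM), NAC-transcription factor 8 in cluster 5 (48.1 CPM) and senescence enhanced2b in cluster 9 (71.3 CPM).

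In the aleurone-like cluster 5, some aleurone regulators, oleosins and defence genes were higher. Viviparous1 (Zm00001d042396), a seed maturation regulator, was 6.76-fold (4.61 to 9.66) above other nuclei, oleosin4 4.57-fold (3.07 to 6.60) and oleosin1 2.04-fold (1.32 to 3.03). Naked endosperm1 was 1.74-fold (1.54 to 1.95) higher, but 0.902-fold in the merged cluster of resolution 0.25. Crinkly4, also counted as a raised marker, was at 2.29-fold (0.606 to 6.12) on 4 UMIs. The other detected aleurone markers were not raised here. These were aleurone9, naked endosperm2 and supernumerary aleurone1, which were highest in clusters 2, 10 and 12. The storage protein gene globulin1 was 6.30-fold (5.44 to 7.26) higher, and it alone carried the embryo list, which stood at 3.79-fold (3.31 to 4.34) with it and 0.582-fold without it. The oil body and globulin list as a whole was at 1.05-fold (0.962 to 1.15), and at 5.07-fold without its most abundant member. That member, globulin3, was at 0.523-fold (0.456 to 0.597), but at 1.06-fold to 1.38-fold under 3 other settings, and is named here after its values were seen. NAC-transcription factor 8 (Zm00001d037315) was 12.6-fold (9.34 to 16.8) higher on 63 UMIs, against its list, which was lower at 0.787-fold (0.757 to 0.817) with 3 of 56 members at least 2-fold higher and 12 at least 2-fold lower. Defence genes summed to 1036 CPM against 482.1, a fold of 2.15 (2.03 to 2.27), with 4 of 6 detected members at least 2-fold higher. Defensin-like protein1 and defensin-like protein2 were 3.25-fold (2.90 to 3.64) and 2.13-fold (1.94 to 2.33) higher, and pathogenesis-related protein2 was 2.13-fold (1.89 to 2.39). With 15 components, where clusters 4 and 5 again shared a match (Jaccard index 0.509 with cluster 5), the defence list was at 1.37-fold and the defensin-like genes at 1.59-fold and 1.26-fold. Markers of endosperm adjacent to scutellum were also higher in cluster 5, at 2.04-fold (1.53 to 2.67).

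Starchy programmes were lower in cluster 5. The 13 starchy endosperm markers stood at 0.486-fold (0.478 to 0.495), starch synthesis genes at 0.457-fold (0.441 to 0.474) and zeins, the main storage proteins, at 0.628-fold (0.617 to 0.638). Within the starch list, sucrose synthase1 went the other way at 4.96-fold (4.57 to 5.36), as did isoamylase-type starch debranching enzyme3 at 3.64-fold (2.89 to 4.55) and granule-bound starch synthase1b at 2.87-fold (2.25 to 3.61). Genes chosen after their values were seen included glossy13 at 12.1-fold (11.5 to 12.8), bZIP-transcription factor 7 at 13.1-fold (12.01 to 14.3) and SWEET4a at 11.9-fold (8.79 to 15.8). In the cluster of resolution 0.25 that merged clusters 4 and 5, folds were 3.02 for viviparous1, 3.07 for NAC-transcription factor 8, 0.803 for starch synthesis and 1.13 for zeins. With 15 components they were 3.79, 4.17, 0.695 and 0.982.

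In cluster 8, the deepest by median, starch genes made up more of the RNA. The 10 starch synthesis genes summed to 9108 CPM against 4081, a fold of 2.23 (2.21 to 2.25), yet the median member had a log2 fold of −0.34, at the 2.82nd percentile, so sum and median differed in sign. Abundant members carried the sum. Pullulanase-type starch debranching enzyme1 was at 5640 CPM and 2.86-fold (2.83 to 2.89), and starch synthase I at 2.36-fold (2.32 to 2.39). Among markers outside that list, dull endosperm1, a starch synthase, was 3.46-fold (3.40 to 3.52) higher. Shrunken2, a subunit of ADP-glucose pyrophosphorylase, was 2.09-fold (2.08 to 2.11) higher and amylose extender1, a branching enzyme, 1.92-fold (1.89 to 1.94). The starchy marker list stood at 1.68-fold (1.67 to 1.69), and 6 of 13 markers were highest in this cluster. NAC-transcription factor 48 (Zm00001d031655) was 3.02-fold (2.89 to 3.15) higher and autophagy18h 2.03-fold (1.95 to 2.10). Among nuclei with at most 50000 UMIs the fold of dull endosperm1 was 5.65 and that of NAC-transcription factor 48 4.72.

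Among clusters, NAC transcripts made up the largest part of UMIs in cluster 3, where zeins were also higher. The 124 NAC genes of the list summed to 3994 CPM against 2524, a fold of 1.58 (1.56 to 1.61). Without NAC-transcription factor 130, the member with most UMIs, the list was at 1.17-fold. Of the 56 members with at least 50 UMIs, 4 were at least 2-fold higher and 3 at least 2-fold lower. NAC-transcription factor 130 (Zm00001d008403) reached 2018 CPM, 2.43-fold (2.38 to 2.48). The gene no-apical-meristem-related protein1 was at 2.74-fold (2.65 to 2.84). It is on the imprinted list and not on the NAC list, so it took no part in the NAC sum. Imprinted genes stood at 1.77-fold (1.72 to 1.82), but at 0.855-fold without no-apical-meristem-related protein1. Fertilization independent endosperm1 was 1.83-fold (1.67 to 2.00) higher. Zeins stood at 1.35-fold (1.34 to 1.36), with zein polypeptidesL2a at 2.89-fold (2.83 to 2.96) and 50kD gamma zein at 2.07-fold (2.02 to 2.12), in a family whose counts are uncertain. Heat shock genes were at 1.49-fold (1.46 to 1.52), ethylene genes at 1.21-fold (1.16 to 1.27), and 60S ribosomal protein L5-1 homolog a at 2.34-fold (2.29 to 2.38). A single nucleus of 708348 UMIs held 12.7% of the cluster's UMIs.

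Cluster 9, with 3.63% of nuclei (3.06 to 4.27), was led by MADS and YABBY genes among others, and cell death proteases were higher in it. Whether its nuclei are of endosperm or of another tissue stays open, as described in the last section. The levels of cell death and other genes in cluster 9 may therefore not describe endosperm. Zea mays MADS6 (Zm00001d031620) was 18.2-fold (15.7 to 20.97) above other nuclei, Zea mays MADS7 27.1-fold (21.8 to 33.4), C2C2-YABBY-transcription factor 5 29.1-fold (24.2 to 34.9) and Zea AGAMOUS homolog2 14.6-fold (11.6 to 18.2). Zea mays MADS8 and Zea mays MADS24, chosen after their values were seen, were 43.5-fold (29.4 to 64.0) and 32.0-fold (23.6 to 43.0) higher. Genes of other kinds among the leading ones were plasma membrane intrinsic protein1 (Zm00001d002690), an aquaporin, at 16.2-fold (12.7 to 20.5) and, also chosen afterwards, aldehyde dehydrogenase3 at 30.5-fold (23.1 to 39.9) and lipoxygenase6 at 27.6-fold (17.7 to 42.4). Without thinning, UMIs of Zea mays MADS6 were present in 82 of 139 nuclei (59.0%), against 3.66% in cluster 2 and 5.56% in cluster 1. Median depths were 3525, 2135 and 4731 UMIs. The leading genes were open to clustering, so these levels and shares are not independent of the cluster. The cell death list summed to 194.6 CPM against 42.1, a fold of 4.63 (3.92 to 5.43), and 6 of 6 detected members were at least 2-fold higher. Senescence enhanced2b (Zm00001d044495), a protease of the vacuolar processing kind, was 14.9-fold (11.03 to 19.9) higher on 59 UMIs and cysteine protease1 3.48-fold (2.53 to 4.66). SWEET1a was 12.4-fold (8.57 to 17.4) higher and beta expansin2, a wall-loosening protein, 4.79-fold (3.35 to 6.66).

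Transfer layer and wall genes were also higher in cluster 9, and several abundant groups depended on how it was drawn. The basal endosperm transfer layer list was at 2.23-fold (1.98 to 2.51) with 8 of 13 members at least 2-fold higher, among them basal endosperm transfer layer9 at 2.97-fold (2.44 to 3.60) and basal endosperm transfer layer3 at 3.87-fold (2.83 to 5.18). With separate UMIs for clusters and levels, these genes were at 1.61-fold and 2.23-fold, while the list rose to 5.14-fold with 15 components. Invertases, which cleave sucrose, were at 2.52-fold (1.80 to 3.44) and cell wall modification genes at 1.77-fold (1.45 to 2.13). Invertases were at 9.30-fold with 15 components and 4.74-fold as a mean over nuclei, and wall genes at 3.30-fold without their most abundant member. The 1 detected gene of the embryo surrounding region does not support a name, and its list stood at 2.30-fold (0.735 to 5.49). Zeins were at 1.50-fold (1.48 to 1.52), core histones at 1.47-fold (1.36 to 1.59) and ribosomal proteins at 1.51-fold (1.48 to 1.54). Zeins stood between 0.811-fold and 0.891-fold and core histones between 0.829-fold and 0.948-fold under 5 other settings each, and ribosomal proteins at 0.989-fold under 1. Starchy endosperm markers were at 0.790-fold (0.776 to 0.803).

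The cycling-like cluster 10 held higher cell cycle transcripts. The list summed to 397.2 CPM against 170.7, a fold of 2.33 (2.06 to 2.62), and 12 of 16 detected members were at least 2-fold higher. Cyclin3 was 28.0-fold (15.6 to 48.3) higher on 19 UMIs and cyclin9 14.7-fold (9.27 to 22.6) on 26. Replication licensing genes minichromosome maintenance1, minichromosome maintenance4 and minichromosome maintenance5 were 7.87-fold (4.70 to 12.5), 4.54-fold (2.74 to 7.13) and 6.88-fold (4.12 to 10.9) higher on 20 UMIs each. With 1000 variable genes (Jaccard index 0.616), minichromosome maintenance4 was at 2.26-fold and minichromosome maintenance5 at 2.98-fold. Kinesin-related protein13, chosen after its values were seen, was 29.2-fold (20.4 to 41.1) higher. The cycling marker list, mostly histones, stood at 1.42-fold (1.32 to 1.53). With clusters and levels from separate UMIs, the best match was a small part of cluster 10. It held 19 nuclei, all among the 96 of cluster 10 (Jaccard index 0.198). The 3 licensing genes had no UMIs in this match. There cyclin3 was at 185.2-fold, cyclin9 at 76.7-fold, kinesin-related protein13 at 149.2-fold and the list at 5.01-fold.

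**Figure D3:**
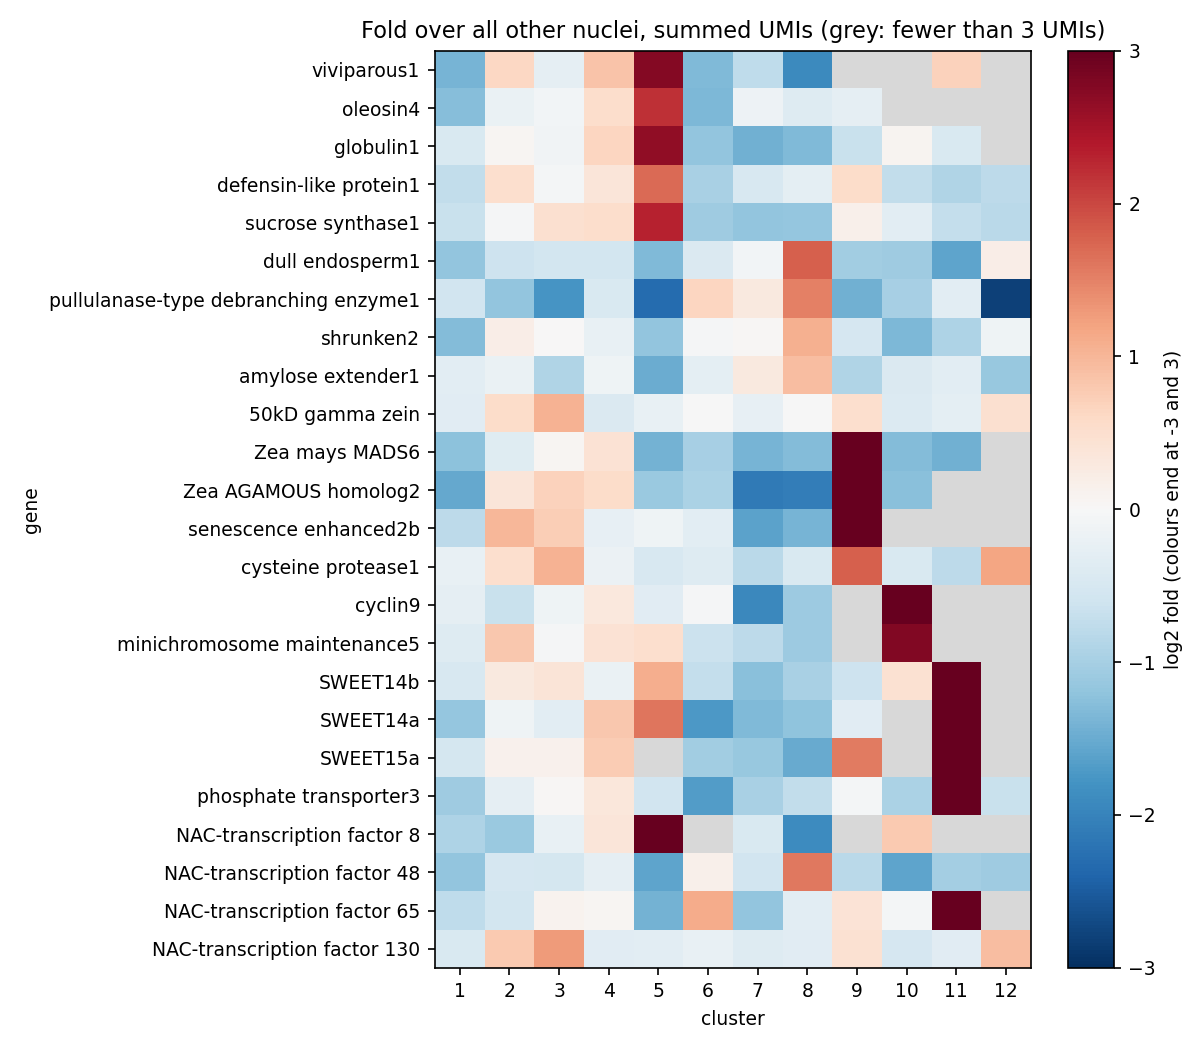
Log2 fold of 24 genes in each cluster over all other nuclei of replicate 1, from summed UMIs (red, higher; blue, lower; grey, fewer than 3 UMIs). Viviparous1 is highest in cluster 5 (6.76-fold), dull endosperm1 in cluster 8 (3.46-fold), Zea mays MADS6 in cluster 9 (18.2-fold) and SWEET14b in cluster 11 (23.6-fold).

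In cluster 12, 31 nuclei, 89 genes reached 4-fold and 100 CPM, among them the unnamed gene Zm00001d002325 at 62030 CPM, 48.6-fold (47.4 to 49.9), which ranged from 16160 to 259100 CPM over its nuclei against a median of 994 CPM elsewhere. Multidrug resistance associated protein2 was 18.0-fold (13.3 to 23.9) and acetyl-coenzyme A carboxylase1, chosen after its values were seen, 11.6-fold (10.0 to 13.3) higher there. Cluster 12 had a match with a Jaccard index of at least 0.5 under 9 of 10 settings. It was not recovered with separate UMIs for clusters and levels (0.073), where its best match was that of cluster 3, with 422 nuclei and Zm00001d002325 at 2.76-fold. In the shallow cluster 2, ribosomal proteins were at 1.45-fold (1.43 to 1.47) and delta zein structural18 at 1.73-fold (1.65 to 1.82), while the 10 zeins together were at 1.04-fold (1.03 to 1.05), and at 0.989-fold with separate UMIs. The 1 gene of cluster 2 at 4-fold and 100 CPM was the feature Plant_SRP, at 7.35-fold (6.91 to 7.815). In cluster 7 the 3 such genes were ribosomal RNA features (SSU_rRNA_eukarya), at 5.31-fold (5.11 to 5.515), 4.95-fold (4.66 to 5.24) and 4.07-fold (3.75 to 4.42). Enhancer of zeste1 was at 1.64-fold (1.56 to 1.72) in cluster 7. It was at 0.927-fold in the best match of that cluster, a poor one (Jaccard index 0.249), when clusters came from 1000 UMIs per nucleus. Of the 64 nuclei in that match, 58 were of cluster 7.

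Cluster 4 held 8.27% of nuclei and 35.4% of UMIs. Core histones there were at 1.36-fold (1.33 to 1.39) and oil body and globulin genes at 1.46-fold (1.42 to 1.50). Cluster 4 was not recovered when clusters came from 1000 UMIs per nucleus, where its best match was that of cluster 1 (Jaccard index 0.097) and had these lists at 0.856-fold and 0.753-fold. Opaque endosperm2, a storage protein regulator, was at 1.46-fold (1.44 to 1.48), miniature seed1, a cell wall invertase, at 2.61-fold (2.13 to 3.21) and sucrose transporter7, chosen after its values were seen, at 9.02-fold (7.30 to 11.2). In its match at resolution 1.0 (Jaccard index 0.777) these 3 genes were at 1.198-fold, 1.11-fold and 1.34-fold. With 1000 variable genes (0.585) they were at 1.24-fold, 1.11-fold and 1.49-fold. All 3 thus depended on how the cluster was drawn, the last 2 most. When nuclei with at most 50000 UMIs were clustered alone, clusters 4 and 5 had the same best match (Jaccard index 0.369 and 0.567), in which these 3 genes stood at 0.913-fold, 0.562-fold and 0.685-fold. Lists with small differences were autophagy, highest in cluster 6 at 1.17-fold (1.14 to 1.21) and at 0.988-fold in the cluster of 1420 nuclei that was its best match at resolution 0.25 (Jaccard index 0.173), and lipases, at 1.34-fold (1.24 to 1.45) in cluster 6 and 0.963-fold without their most abundant member. The aleurone list was at 1.57-fold (1.45 to 1.70) in cluster 5, auxin genes at 2.44-fold (1.88 to 3.12) in cluster 11, carried by auxin transporter-like1, and the scutellum-side marker list at 18.6-fold (15.5 to 22.2) there. Green maternal tissue markers reached at most 2.32-fold (0.615 to 6.21), in cluster 5 on 4 UMIs, a difference not detectable at this depth.

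The barcode lists allowed the 3 libraries to be set side by side. Filtered lists held 3842, 14412 and 13783 barcodes in replicates 1, 2 and 3, out of 3256205, 2651479 and 2853349 raw barcodes, and every filtered barcode was in its raw list. Overlaps were set against independent draws from the 4307953 barcodes present in any of the raw lists. Replicates 1 and 2 shared 16 filtered barcodes (9.15 to 26.0) against 12.9 under independence, and replicates 1 and 3 shared 11 (5.49 to 19.7) against 12.3. Replicates 2 and 3 shared 59 (44.9 to 76.1) against 46.1, within counting error of that expectation. Possible barcodes absent from the raw lists were not counted. A larger set would lower the expected overlaps, so whether 59 exceeds independence is not settled.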

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

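The tests with at most 50000 UMIs per nucleus, without the upper 5% of Scrublet scores and with clusters from 1000 UMIs per nucleus were chosen only after the data were seen. No paired analysis was made because there is 1 group, and only counts of replicate 1 were analysed here, so no replicate was left out in turn. Doublets kept and a minimum of 1000 UMIs removed no nuclei and say nothing about stability. The number of clusters ran from 10 to 18 around 12. Each cluster was followed by its best match in nuclei, and a Jaccard index under 0.5 is called a poor match. The value of a poor match may belong to another cluster or to a small part of the same one. With separate UMIs, all 19 nuclei in the match of cluster 10 were of cluster 10. In that of cluster 6, 128 of 135 were of cluster 6. With 1000 UMIs per nucleus, 58 of 64 nuclei in the match of cluster 7 were of cluster 7. Clusters 2, 3, 9 and 11 had an index of at least 0.5 under 10 of 10 settings, cluster 7 under 2. Clusters 4 and 5 shared 1 match of 560 nuclei at resolution 0.25, 499 with 15 components, 491 with separate UMIs and 442 with at most 50000 UMIs, so their values there describe a merged cluster. Cluster 4 with 1000 UMIs per nucleus (0.097) and clusters 6 and 7 at resolution 0.25 (0.173 and 0.138) had the match of cluster 1. Of the 193 gene values that the naming rule gave, 42 reversed under at least 1 setting, among them 14 of 45 in cluster 9, 13 of 28 in cluster 10, 9 of 10 in cluster 4 and 0 of 13 in cluster 11. By setting, 28 reversed with separate UMIs, 25 with 1000 UMIs per nucleus, 11 with 15 components, 9 with 1000 variable genes, 8 at resolution 1.0, 3 with at most 50000 UMIs and 2 at resolution 0.25. Of the 69 genes named in the text, picked after such values were seen, 9 reversed, and of 38 list levels 11 did. The cause of the changes below was not tested.

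Shares of nuclei, in percent, that left their 95% intervals were as follows. Cluster 1 (25.3) changed to 37.1 (resolution 0.25), 20.0 (1000 variable genes), 18.2 (15 components), 20.9 (all genes), 17.9 (separate UMIs), 21.3 (seed 1), 20.96 (up to 50000 UMIs), 17.9 (lower Scrublet scores) and 33.97 (1000 UMIs), and in poor matches to 11.1 (resolution 1.0). Cluster 2 (24.2) changed to 26.7 (1000 variable genes), 25.7 (all genes), 30.7 (separate UMIs), 26.4 (lower Scrublet scores) and 30.5 (1000 UMIs). Cluster 3 (9.58) changed to 11.01 (separate UMIs), 8.45 (lower Scrublet scores) and 8.40 (1000 UMIs). Cluster 4 (8.27) changed to 14.6 (resolution 0.25), 6.52 (resolution 1.0), 5.37 (1000 variable genes), 6.60 (all genes), 6.496 (seed 1) and 6.67 (lower Scrublet scores), and in poor matches to 13.02 (15 components), 12.8 (separate UMIs), 12.1 (up to 50000 UMIs) and 33.97 (1000 UMIs). Cluster 5 (6.71) changed to 8.09 (1000 variable genes), 13.02 (15 components), 7.75 (all genes), 7.91 (seed 1), 12.1 (up to 50000 UMIs) and 7.57 (1000 UMIs), and in poor matches to 14.6 (resolution 0.25) and 12.8 (separate UMIs). Cluster 6 (6.57) changed to 5.19 (1000 variable genes) and 4.67 (all genes), and in poor matches to 37.1 (resolution 0.25), 3.52 (separate UMIs) and 12.7 (1000 UMIs). Cluster 7 (5.92) changed to 3.71 (resolution 1.0) and 9.31 (seed 1), and in poor matches to 37.1 (resolution 0.25), 9.50 (1000 variable genes), 10.9 (15 components), 10.9 (all genes), 7.83 (separate UMIs), 11.6 (up to 50000 UMIs), 11.6 (lower Scrublet scores) and 1.67 (1000 UMIs). Cluster 8 (5.04) changed to 6.16 (resolution 1.0), 8.35 (1000 variable genes), 8.14 (15 components), 9.34 (separate UMIs) and 3.45 (up to 50000 UMIs), and in poor matches to 12.7 (1000 UMIs). Cluster 9 (3.63) changed to 2.97 (resolution 1.0), 2.95 (1000 variable genes), 4.38 (up to 50000 UMIs) and 2.45 (1000 UMIs). Cluster 10 (2.51) changed in poor matches alone, to 0.496 (separate UMIs) and 0.678 (1000 UMIs). Cluster 11 (1.41) changed to 1.04 (1000 UMIs). Cluster 12 (0.809) changed in poor matches alone, to 11.01 (separate UMIs).

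List levels, as folds over other nuclei, that left their intervals follow in the same way. They cover each list in the cluster where it was highest and further ones chosen after the data were seen, and no top member means without the most abundant gene. NAC transcription factors in cluster 3 (1.58) changed to 1.67 (up to 50000 UMIs), 1.62 (lower Scrublet scores), 1.70 (1000 UMIs), 1.51 (mean over nuclei) and 1.17 (no top member). SWEET sugar transporters in cluster 11 (4.76) changed to 6.31 (1000 UMIs) and 5.87 (no top member). Aleurone in cluster 5 (1.57) changed to 1.19 (15 components), 1.44 (seed 1), 1.27 (up to 50000 UMIs) and 1.44 (no top member), and in poor matches to 1.10 (resolution 0.25) and 1.15 (separate UMIs). Autophagy in cluster 6 (1.17) changed to 1.13 (up to 50000 UMIs), and in poor matches to 0.988 (resolution 0.25) and 1.09 (1000 UMIs). Auxin in cluster 11 (2.44) changed to 1.77 (separate UMIs) and 5.32 (no top member). Basal endosperm transfer layer in cluster 9 (2.23) changed to 1.97 (1000 variable genes), 5.14 (15 components), 1.52 (separate UMIs), 1.79 (1000 UMIs), 2.56 (mean over nuclei) and 2.67 (no top member). Cell cycle in cluster 10 (2.33) changed to 2.81 (no top member), and in poor matches to 5.01 (separate UMIs) and 3.58 (1000 UMIs). Cell death proteases and nucleases in cluster 9 (4.63) changed to 6.47 (resolution 1.0), 6.07 (1000 variable genes), 5.58 (15 components) and 6.21 (1000 UMIs). Cell wall modification in cluster 9 (1.77) changed to 2.33 (resolution 1.0), 2.28 (1000 variable genes), 2.43 (1000 UMIs), 2.68 (mean over nuclei) and 3.30 (no top member). Core histones in cluster 9 (1.47) changed to 1.34 (resolution 0.25), 0.948 (resolution 1.0), 0.932 (1000 variable genes), 0.878 (15 components), 0.886 (separate UMIs), 1.28 (seed 1), 0.829 (1000 UMIs) and 1.35 (mean over nuclei). Cycling in cluster 10 (1.42) changed to 1.31 (1000 variable genes), 1.54 (up to 50000 UMIs) and 1.57 (mean over nuclei), and in poor matches to 1.66 (separate UMIs). Defence proteins in cluster 5 (2.15) changed to 1.82 (1000 variable genes), 1.37 (15 components), 1.88 (all genes), 1.82 (seed 1), 1.63 (up to 50000 UMIs), 1.94 (lower Scrublet scores) and 1.85 (1000 UMIs), and in poor matches to 1.51 (resolution 0.25) and 1.39 (separate UMIs). Embryo in cluster 5 (3.79) changed to 3.17 (1000 variable genes), 1.88 (15 components), 3.17 (all genes), 3.08 (seed 1), 2.56 (up to 50000 UMIs), 3.18 (1000 UMIs) and 0.582 (no top member), and in poor matches to 1.77 (resolution 0.25) and 2.11 (separate UMIs). Endosperm adjacent to scutellum in cluster 11 (18.6) changed to 23.8 (1000 UMIs) and 15.1 (no top member). Ethylene in cluster 3 (1.21) changed to 1.15 (mean over nuclei) and 1.36 (no top member). Green maternal tissue in cluster 5 (2.32) changed to 0.0 (no top member). Heat shock proteins in cluster 3 (1.49) changed to 1.62 (up to 50000 UMIs), 1.52 (lower Scrublet scores), 1.52 (1000 UMIs) and 1.42 (no top member). Imprinted genes in cluster 3 (1.77) changed to 1.82 (lower Scrublet scores), 1.88 (1000 UMIs), 1.64 (mean over nuclei) and 0.855 (no top member). Invertases in cluster 9 (2.52) changed to 3.82 (resolution 1.0), 3.70 (1000 variable genes), 9.30 (15 components), 3.49 (1000 UMIs) and 4.74 (mean over nuclei). Lipases and phospholipases in cluster 6 (1.34) changed to 1.17 (up to 50000 UMIs) and 0.963 (no top member), and in poor matches to 1.196 (resolution 0.25), 1.55 (separate UMIs) and 1.18 (1000 UMIs). Oil body and seed globulins in cluster 4 (1.46) changed to 1.21 (resolution 1.0), 1.24 (1000 variable genes), 1.27 (mean over nuclei) and 1.52 (no top member), and in poor matches to 1.198 (15 components), 1.22 (separate UMIs), 1.26 (up to 50000 UMIs) and 0.753 (1000 UMIs). Ribosomal proteins in cluster 9 (1.51) changed to 1.47 (resolution 0.25), 1.13 (resolution 1.0), 1.11 (1000 variable genes), 1.10 (15 components), 1.46 (all genes), 0.989 (separate UMIs), 1.35 (seed 1), 1.33 (up to 50000 UMIs), 1.11 (1000 UMIs) and 1.25 (mean over nuclei). Starch synthesis in cluster 8 (2.23) changed to 1.98 (resolution 1.0), 2.03 (1000 variable genes), 2.03 (15 components), 2.02 (separate UMIs), 2.95 (up to 50000 UMIs), 2.98 (mean over nuclei) and 1.65 (no top member), and in poor matches to 2.06 (1000 UMIs). Starchy endosperm in cluster 8 (1.68) changed to 1.62 (resolution 1.0), 1.62 (1000 variable genes), 1.63 (15 components), 1.63 (separate UMIs), 2.18 (up to 50000 UMIs), 1.95 (mean over nuclei) and 1.96 (no top member), and in poor matches to 1.56 (1000 UMIs). Zeins in cluster 9 (1.50) changed to 1.42 (resolution 0.25), 0.891 (resolution 1.0), 0.874 (1000 variable genes), 0.868 (15 components), 1.42 (all genes), 0.811 (separate UMIs), 1.28 (seed 1), 1.43 (up to 50000 UMIs), 1.44 (lower Scrublet scores), 0.825 (1000 UMIs), 1.27 (mean over nuclei) and 1.56 (no top member). Zeins in cluster 3 (1.35) changed to 1.34 (1000 variable genes), 1.34 (15 components), 1.34 (separate UMIs), 1.58 (up to 50000 UMIs), 1.37 (lower Scrublet scores), 1.45 (mean over nuclei) and 1.33 (no top member). Zeins in cluster 5 (0.628) changed to 0.599 (1000 variable genes), 0.982 (15 components), 0.615 (all genes), 0.828 (up to 50000 UMIs), 0.583 (lower Scrublet scores), 0.640 (1000 UMIs), 0.724 (mean over nuclei) and 0.642 (no top member), and in poor matches to 1.13 (resolution 0.25) and 0.988 (separate UMIs). Ribosomal proteins in cluster 2 (1.45) changed to 1.51 (1000 variable genes), 1.34 (separate UMIs), 1.49 (up to 50000 UMIs), 1.36 (1000 UMIs) and 1.41 (mean over nuclei). Core histones in cluster 4 (1.36) changed to 1.31 (resolution 0.25), 1.19 (resolution 1.0), 1.21 (1000 variable genes) and 1.17 (mean over nuclei), and in poor matches to 1.13 (15 components), 1.13 (separate UMIs), 1.08 (up to 50000 UMIs) and 0.856 (1000 UMIs). Starch synthesis in cluster 5 (0.457) changed to 0.519 (1000 variable genes), 0.695 (15 components), 0.549 (all genes), 0.550 (seed 1), 0.756 (up to 50000 UMIs), 0.508 (lower Scrublet scores), 0.541 (1000 UMIs), 0.575 (mean over nuclei) and 0.747 (no top member), and in poor matches to 0.803 (resolution 0.25) and 0.6996 (separate UMIs). Starchy endosperm in cluster 5 (0.486) changed to 0.737 (15 components), 0.522 (all genes), 0.522 (seed 1), 0.717 (up to 50000 UMIs), 0.540 (1000 UMIs), 0.577 (mean over nuclei) and 0.408 (no top member), and in poor matches to 0.872 (resolution 0.25) and 0.737 (separate UMIs). Starchy endosperm in cluster 9 (0.790) changed to 0.736 (resolution 1.0), 0.722 (1000 variable genes), 0.688 (15 components), 0.776 (all genes), 0.678 (separate UMIs), 0.749 (seed 1), 0.814 (up to 50000 UMIs), 0.693 (1000 UMIs), 0.861 (mean over nuclei) and 0.640 (no top member). Oil body and seed globulins in cluster 5 (1.05) changed to 0.957 (1000 variable genes), 1.198 (15 components), 1.26 (up to 50000 UMIs), 1.36 (mean over nuclei) and 5.07 (no top member), and in poor matches to 1.46 (resolution 0.25) and 1.22 (separate UMIs). Zeins in cluster 2 (1.04) changed to 1.07 (resolution 0.25), 1.204 (1000 variable genes), 1.09 (15 components), 0.989 (separate UMIs), 1.08 (seed 1), 1.24 (up to 50000 UMIs), 1.06 (lower Scrublet scores), 1.39 (1000 UMIs), 1.21 (mean over nuclei) and 1.09 (no top member). NAC transcription factors in cluster 5 (0.787) changed to 0.873 (15 components) and 0.740 (lower Scrublet scores), and in poor matches to 0.879 (resolution 0.25) and 0.864 (separate UMIs). NAC transcription factors in cluster 11 (0.982) changed to 1.08 (1000 UMIs) and 1.09 (no top member). Endosperm adjacent to scutellum in cluster 5 (2.04) changed to 1.46 (15 components) and 1.50 (up to 50000 UMIs), and in poor matches to 1.40 (resolution 0.25).

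Named genes that reversed were these. In the merged cluster of resolution 0.25, naked endosperm1 was at 0.902 and globulin3, lower in cluster 5, at 1.38. The latter was also at 1.06 with 15 components and 1.07 with separate UMIs. The best match of cluster 4 with at most 50000 UMIs, which it shared with cluster 5, had opaque endosperm2 at 0.913, miniature seed1 at 0.562 and sucrose transporter7 at 0.685. With 1000 UMIs per nucleus its match was cluster 1's, at 0.978, 0.815 and 0.813 for these genes, and miniature seed1 was at 0.860 with separate UMIs. Enhancer of zeste1 was at 0.927 with 1000 UMIs per nucleus, in a poor match of cluster 7 (0.249). In poor matches of cluster 10, minichromosome maintenance1, minichromosome maintenance4 and minichromosome maintenance5 were at 0.0 with separate UMIs, and minichromosome maintenance4 at 0.0 with 1000 UMIs per nucleus. The share of nuclei of cluster 11 with SWEET14b was 7.41% after thinning to 500 UMIs and 50% unthinned, against 20.4%, and that with NAC-transcription factor 65 was 38.9% unthinned, against 7.41%.

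Other folds of named genes that moved by over 1.5 times were as follows. Viviparous1 in cluster 5 (6.76) moved to 3.79 (15 components), and in poor matches to 3.02 (resolution 0.25) and 3.92 (separate UMIs). Oleosin4 in cluster 5 (4.57) moved to 1.97 (15 components), and in poor matches to 1.95 (resolution 0.25) and 1.64 (separate UMIs). Naked endosperm1 in cluster 5 (1.74) moved to 1.06 (15 components), and in poor matches to 1.03 (separate UMIs). Globulin1 in cluster 5 (6.30) moved to 2.97 (15 components), and in poor matches to 2.46 (resolution 0.25) and 3.53 (separate UMIs). NAC-transcription factor 8 in cluster 5 (12.6) moved to 4.17 (15 components) and 6.56 (up to 50000 UMIs), and in poor matches to 3.07 (resolution 0.25) and 3.65 (separate UMIs). Sucrose synthase1 in cluster 5 (4.96) moved to 2.46 (15 components) and 3.29 (up to 50000 UMIs), and in poor matches to 2.03 (resolution 0.25) and 2.55 (separate UMIs). Isoamylase-type starch debranching enzyme3 in cluster 5 (3.64) moved to 1.90 (15 components), and in poor matches to 1.54 (resolution 0.25) and 1.95 (separate UMIs). Granule-bound starch synthase1b in cluster 5 (2.87) moved to 1.46 (15 components), and in poor matches to 1.32 (resolution 0.25) and 1.57 (separate UMIs). Defensin-like protein1 in cluster 5 (3.25) moved to 1.59 (15 components) and 2.16 (up to 50000 UMIs), and in poor matches to 1.58 (resolution 0.25) and 1.63 (separate UMIs). Defensin-like protein2 in cluster 5 (2.13) moved to 1.26 (15 components), and in poor matches to 1.42 (resolution 0.25) and 1.27 (separate UMIs). Dull endosperm1 in cluster 8 (3.46) moved to 5.65 (up to 50000 UMIs). Starch synthase I in cluster 8 (2.36) moved to 3.81 (up to 50000 UMIs). NAC-transcription factor 48 in cluster 8 (3.02) moved to 4.72 (up to 50000 UMIs). Zea mays MADS6 in cluster 9 (18.2) moved to 29.5 (resolution 1.0), 30.3 (1000 variable genes), 27.3 (separate UMIs) and 37.1 (1000 UMIs). Zea mays MADS7 in cluster 9 (27.1) moved to 45.2 (resolution 1.0), 46.7 (1000 variable genes) and 51.7 (1000 UMIs). C2C2-YABBY-transcription factor 5 in cluster 9 (29.1) moved to 48.7 (resolution 1.0), 47.2 (1000 variable genes), 47.3 (1000 UMIs) and 48.9 (mean over nuclei). Zea AGAMOUS homolog2 in cluster 9 (14.6) moved to 24.0 (resolution 1.0), 26.3 (1000 variable genes) and 28.1 (1000 UMIs). Senescence enhanced2b in cluster 9 (14.9) moved to 24.1 (resolution 1.0), 23.4 (1000 variable genes) and 22.7 (1000 UMIs). Beta expansin2 in cluster 9 (4.79) moved to 7.39 (mean over nuclei). Basal endosperm transfer layer9 in cluster 9 (2.97) moved to 1.61 (separate UMIs). Basal endosperm transfer layer3 in cluster 9 (3.87) moved to 2.23 (separate UMIs). SWEET1a in cluster 9 (12.4) moved to 20.2 (resolution 1.0), 21.4 (1000 variable genes), 23.4 (1000 UMIs) and 24.9 (mean over nuclei). Cyclin3 in cluster 10 (28.0) moved to 45.3 (mean over nuclei), and in poor matches to 185 (separate UMIs) and 98.0 (1000 UMIs). Cyclin9 in cluster 10 (14.7) moved in poor matches to 76.7 (separate UMIs) and 50.2 (1000 UMIs). Minichromosome maintenance1 in cluster 10 (7.87) moved in poor matches to 1.87 (1000 UMIs). Minichromosome maintenance4 in cluster 10 (4.54) moved to 2.26 (1000 variable genes) and 2.40 (mean over nuclei). Minichromosome maintenance5 in cluster 10 (6.88) moved to 2.98 (1000 variable genes), and in poor matches to 3.32 (1000 UMIs). SWEET15a in cluster 11 (11.2) moved to 17.4 (1000 UMIs) and 20.1 (mean over nuclei). NAC-transcription factor 65 in cluster 11 (14.3) moved to 9.12 (separate UMIs). Male sterile8 in cluster 11 (23.9) moved to 36.5 (1000 UMIs). Auxin transporter-like1 in cluster 11 (10.5) moved to 15.9 (1000 UMIs) and 16.4 (mean over nuclei). Multidrug resistance associated protein2 in cluster 12 (18.0) moved in poor matches to 1.70 (separate UMIs). Zm00001d002325 in cluster 12 (48.6) moved in poor matches to 2.76 (separate UMIs). Miniature seed1 in cluster 4 (2.61) moved to 1.11 (resolution 1.0) and 1.11 (1000 variable genes), and in poor matches to 1.01 (15 components). NAC-transcription factor 36 in cluster 11 (10.5) moved to 20.1 (1000 UMIs). Beta amylase5 in cluster 11 (59.6) moved to 27.8 (separate UMIs) and 108 (1000 UMIs). Glossy13 in cluster 5 (12.1) moved to 7.35 (15 components), and in poor matches to 6.20 (resolution 0.25) and 6.70 (separate UMIs). The gene bZIP-transcription factor 7 in cluster 5 (13.1) moved to 5.68 (15 components), and in poor matches to 4.51 (resolution 0.25) and 5.64 (separate UMIs). SWEET4a in cluster 5 (11.9) moved to 5.21 (15 components), and in poor matches to 4.09 (resolution 0.25) and 4.71 (separate UMIs). Zea mays MADS8 in cluster 9 (43.5) moved to 73.5 (resolution 1.0), 66.2 (1000 variable genes) and 84.4 (mean over nuclei). Zea mays MADS24 in cluster 9 (32.0) moved to 54.0 (resolution 1.0), 53.4 (1000 variable genes), 63.5 (1000 UMIs) and 52.4 (mean over nuclei). Kinesin-related protein13 in cluster 10 (29.2) moved to 49.6 (mean over nuclei), and in poor matches to 149 (separate UMIs) and 79.8 (1000 UMIs). Acetyl-coenzyme A carboxylase1 in cluster 12 (11.6) moved in poor matches to 1.34 (separate UMIs). Sucrose transporter7 in cluster 4 (9.02) moved to 1.34 (resolution 1.0) and 1.49 (1000 variable genes), and in poor matches to 1.25 (15 components) and 1.33 (separate UMIs). Plasma membrane intrinsic protein1 in cluster 9 (16.2) moved to 25.6 (resolution 1.0), 24.7 (1000 variable genes) and 29.8 (1000 UMIs). Aldehyde dehydrogenase3 in cluster 9 (30.5) moved to 47.8 (resolution 1.0), 46.3 (1000 variable genes), 59.4 (1000 UMIs) and 52.2 (mean over nuclei). Lipoxygenase6 in cluster 9 (27.6) moved to 44.6 (resolution 1.0), 43.2 (1000 variable genes), 43.8 (1000 UMIs) and 94.1 (mean over nuclei). Globulin3 in cluster 5 (0.523) moved to 0.952 (up to 50000 UMIs).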

Other observations

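Tests on MADS and YABBY genes in cluster 9 and on random multiplets in cluster 4 were chosen only after the results were seen, while the tests on very deep nuclei and on cluster 2 were written beforehand. Before the latter were written, the levels of ribosomal and organelle transcripts over the whole of cluster 2 had been seen, though not those at matched depth. No biological explanation was tested, since the labels give 1 group.

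MADS and YABBY genes in cluster 9 may come from nuclei of another tissue that carry free endosperm RNA, for which a single source should hold endosperm genes in 1 ratio. Log2 ratios of the 13 starchy endosperm markers to cluster 2 had an SD of 0.234 in cluster 9, below the lowest of the other clusters (0.340) and their median (0.731). By the markers alone, the values went with this explanation. Zeins were added to the test after their ratio to cluster 2 had been seen, and they go against a single ratio. They stood at 1.43 times cluster 2 (1.40 to 1.45) and the markers at 0.816 times (0.800 to 0.832), 1.749 times apart. A criterion picked in this way cannot decide the question. The explanation stays open, because cluster 2 as a stand-in for free RNA is an assumption and the zein level of cluster 9 turned to between 0.811-fold and 0.891-fold of other nuclei under 5 settings. Doublets also stay open, since the doublet caller did not work. The quartiles of cluster 9 (2098 to 7514 UMIs) also hold the median of all kept nuclei (4470). The rule first compared medians, by which the median of cluster 9 (3525 UMIs) went against doublets. It was changed to quartiles after the depths had been seen, because sums of 2 shallow nuclei can lie below the median of all nuclei.

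Genes leading cluster 5 were also raised in cluster 4, where they could reflect multiplets or a few very deep nuclei. The 25 leading genes of clusters 5, 9, 10 and 11 stood in cluster 4, with its nuclei of all depths pooled, at 1.64, 1.07, 1.27 and 1.16 times the summed other nuclei. The highest and lowest differed by 1.529 times with intervals that did not overlap (1.57 to 1.71 and 1.00 to 1.14), which random draws would not give, but by less than the bound of 2 set for this test, so random multiplets remain open. A few very deep nuclei are argued against, since the genes of cluster 5 were 8.615 times as high as in cluster 1 (7.62 to 9.76) among 237 nuclei with at most 50000 UMIs, against 4.50 times (4.01 to 5.05) among all nuclei. Cluster 1 is a low baseline, since it was below cluster 4 for each of these gene sets.

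Ribosomal protein transcripts, and at matched depth zeins, were higher in the shallow cluster 2, which could follow from depth alone or from cytoplasmic or free RNA. Between 1499 and 2653 UMIs, ribosomal protein transcripts were 1.236 times as high in 465 nuclei of cluster 2 as in 329 of other clusters (1.199 to 1.275). The interval excludes 1, the value depth alone would give, but its lower end missed the bound of 1.2 set beforehand, so depth alone was not ruled out by that bound and stays open. Zeins, looked at afterwards, stood at 1.24 (1.209 to 1.271) at this depth but at 1.042 over all nuclei (1.032 to 1.053), which does not replace that bound. The organelle share was 1.328 times as high (1.285 to 1.373), which is consistent with RNA from outside the nucleus, though organelle genes took part in clustering and the test is partly circular.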
